A study of Mus musculus with 6 samples.

How the data were processed

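RNA was sequenced from 4T1 mouse mammary carcinoma cells in 3D collagen I gels, 3 control samples and 3 ETV4 KO samples, after nucleofection with Cas9 and guide RNAs. Per the labels' protocols, the gels were digested with collagenase I, RNA was extracted on columns with DNase treatment, and libraries were made with a stranded poly(A) kit. The protocol names a pair of collagen concentrations without saying which was used for these samples. Samples were put in groups by their titles, and each column of the deposited table was matched to its sample by the library name in the labels.

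The authors deposited 1 table of raw read counts per gene, with 31017 gene symbols as identifiers and no normalization; the unit was taken from the values, whole numbers that sum to 22355015 to 29042569 per library. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.9a, R 4.1.1 and featureCounts, and the genome builds hg38 and mm10, with no role or order. The annotation, the strand setting, the treatment of reads that map to several places and any read filter are not given in the sources used here. These choices decide how reads of near-identical or overlapping genes are counted, so such genes are uncertain.

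Counts were analysed as deposited with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), library sizes were scaled by TMM, and the groups were compared by glmQLFit and glmQLFTest with the group as the term and no replicate block, with Benjamini-Hochberg adjustment over 12076 genes. A gene was called at an adjusted p under 0.05. Log2 fold changes are ETV4 KO against control, and their SE is the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM uses a pseudocount of 0.5. For a gene with 0 counts in one group the fold is a bound with 3 counts over that group as the floor, and for a gene with 1 to 3 counts a 95% Clopper-Pearson interval of the count ratio is given; both cover counting error only. Summed marker levels of other cell types use raw library sizes.

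The 38 gene lists, the tests, the rule for named genes and most alternatives were set before the data were examined. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists tested, and again with an estimated correlation and by fry. Where a list was not called, its median, its mean and the direction of its test can differ in sign; this was so for the lists of growth factor ligands and receptors, protease inhibitors, basal and luminal mammary genes, Notch, chemokines and cytokines, semaphorins and ephrins, and histones, for which no direction is given. For no called list did they differ. The named genes are Etv4, Etv1 and Etv5; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean count is at least 100 in the higher group, leaving out symbols without a function name; and, per list that was called or had 3 called members, up to 3 called members with the smallest adjusted p in the majority direction and 1 in the other. Genes outside this rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

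Gene positions were taken from GENCODE M21 (GRCm38, equal to mm10) by symbol, which gave 1 position for 30416 of the 31017 symbols. The median log2 fold change of genes with an edgeR log2 CPM above 3 was computed per chromosome, with 1000 bootstrap resamples over genes, and per 10 Mb bin with at least 10 genes. For the bin alternative, the median of the other expressed genes in a gene's bin, or of its chromosome where the bin held fewer than 10, was entered as an offset of the ETV4 KO libraries. The SEs and p-values of the bin alternative treat that median as known. They leave out its error and the spread of the genes around it, so a call alone does not set a gene apart from its neighbours. This alternative and the matching of newer to older symbols were chosen after seeing the data.

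The alternatives were edgeR with RLE and upper-quartile factors and with library size only, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of CPM of at least 1 in at least 3 samples, a replicate block, each sample left out in turn, an adjusted p under 0.01, glmTreat against a fold change of 1.5, and mitochondrial genes left out before normalization. The steps were tested on simulated counts for the 12076 genes, drawn from the control means, the library sizes and the trended dispersion, with 200 genes changed. Of 50 genes per fold size edgeR recovered 64% at 1.2-fold, 88% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, and it called 12 of the 11876 unchanged genes. Of the 2-fold genes 43 of 45 with a mean of at least 20 counts per control library were recovered, and 0 of 5 below that, so that depth limits low-count genes. Camera called the raised list and 0 of 33 unchanged lists. Genes were drawn independently of each other, so this cannot check the preset correlation of 0.01 on which the list calls rest. Nearly all simulated genes were unchanged, whereas 71.1% of the tested genes were called in the data, so the recovery rates may differ there. With chromosome 11 lowered by 0.4 in the simulation, the recovered median was -0.40 over its otherwise unchanged genes, and of the 980 of these that passed the filter 84.3% were called before and 0.102% after the bin medians were taken out. Each of these genes was lowered by the same amount. The simulation therefore cannot show how the step acts where genes spread around the median, as in the data.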

Results

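Poly(A) RNA was sequenced from 4T1 cells, a mouse mammary carcinoma line, that had been nucleofected with Cas9 and guide RNAs and then grown in 3D collagen I gels. The gels were digested with collagenase before RNA was extracted. The series held 6 samples in 2 groups. The 3 control samples received control guides, and the 3 ETV4 KO samples are named for the knockout of Etv4, which encodes an ETS transcription factor of the PEA3 subfamily. The comparison asked which transcripts differ between ETV4 KO and control cells in this culture. The total counts were 22742579, 26669985 and 22355015 in control replicates 1, 2 and 3, and 29042569, 25296874 and 24356286 in ETV4 KO replicates 1, 2 and 3. Between 15515 and 15800 genes had at least 1 count per library, and 12076 of the 31017 genes in the table passed the filter and were tested.

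In ETV4 KO cells, interferon-stimulated and antigen presentation genes were lower, with 40 of 44 tested members called lower and 1 called higher. Epithelial genes were more often lower than higher, including Rab25 with a log2 fold change of -7.69 (SE 0.14, n = 3 per group; -8.58 without ETV4 KO replicate 1) and Cldn7 with -5.92 (SE 0.061, n = 3 per group). Genes for proteases and the mesenchymal state were mostly higher, including Mmp3 at 2.36 (SE 0.046, n = 3 per group), although Mmp9 had -1.27. Of 23 collagen and basement membrane genes 12 were called higher and 4 lower. These lists were called by camera with a preset correlation, whereas 0 lists were called with an estimated one. Etv4 mRNA itself was lower by less than 2-fold, and so were most genes near it on chromosome 11.

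The samples of a group were close to each other. Pearson's r of log2 CPM across genes lay between 0.9978 and 0.9981 within a group and between 0.9688 and 0.9699 between groups, and the first principal component held 91.4% of the variance. The chi-square statistic of the counts per degree of freedom was 2.12 to 5.16 for pairs within a group, above the value of 1 that sampling noise gives, so no library appeared to have been deposited more than once. For pairs between groups it was 71.6 to 91.6. The 3 ETV4 KO libraries share 1 library code, and the 3 control libraries share another, sgCTRL. What the ETV4 KO code stands for is not given in the sources used here. The labels also do not say whether the 3 samples of a group were separate cultures. The p-values below therefore measure only the spread between these samples, which may be technical.

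The targeted gene was lower in each ETV4 KO library than in each control library. Etv4 (chromosome 11, 101769742 to 101785371 in mm10) had 3098, 3648 and 3030 counts in the controls and 2503, 2217 and 2207 counts in ETV4 KO. The TMM-scaled means were 133.9 CPM ± 0.752 (SD, n = 3) and 89.8 CPM ± 2.44 (SD, n = 3), a log2 fold change of -0.58 (SE 0.036, edgeR quasi-likelihood adjusted p = 1.03e-14). Counts over a whole gene do not show whether a Cas9 cut changed the protein, and the position of the guides is not given in the sources used here. Of the other PEA3 members, Etv5 (chromosome 16) was lower, with 54.6 CPM ± 2.57 (SD, n = 3) in controls, 34.7 CPM ± 0.708 (SD, n = 3) in ETV4 KO and a log2 fold change of -0.65 (SE 0.049, edgeR adjusted p = 6.34e-13). Etv1 (chromosome 12) had a log2 fold change of -0.10 (SE 0.041, edgeR adjusted p = 0.0262), a call that 9 of the 14 alternatives in processing or samples kept; it was lost without control replicate 1 (adjusted p = 0.0614), without control replicate 3 (0.161) and without ETV4 KO replicate 3 (0.104), among others. The expressed genes of chromosome 11 had a median log2 fold change of -0.38, and those within 10 Mb of Etv4 a median of -0.41. An alternative chosen after seeing the data took out the median of each gene's 10 Mb bin. The log2 fold change of Etv4 was then -0.11 (SE 0.036, edgeR adjusted p = 0.0074) and that of Etv1 was -0.19. This SE and p take the bin median as known and leave out the spread of the genes around it. The expressed genes within 10 Mb of Etv4 ran from -1.06 to 0.30 (5th to 95th percentile), so Etv4 was not set apart from them.

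**Figure D1:**
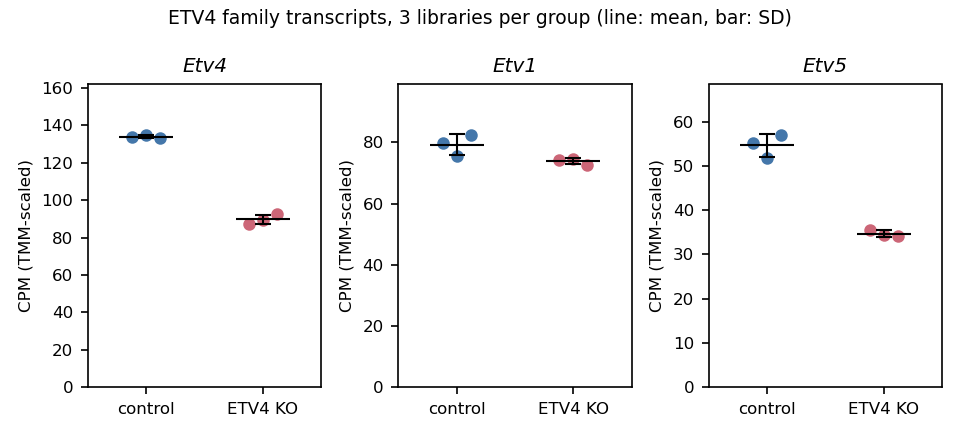
TMM-scaled CPM (vertical axes from 0) of Etv4, Etv1 and Etv5 in the 3 control libraries (blue) and the 3 ETV4 KO libraries (red), with the mean as a line and the SD as a bar. Etv4 averaged 133.9 CPM in controls and 89.8 CPM in ETV4 KO, Etv1 79.2 and 73.7 CPM, and Etv5 54.6 and 34.7 CPM.

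The groups differed over most of the expressed genome. In ETV4 KO 4232 genes were higher and 4350 lower at an edgeR adjusted p under 0.05, together 8582 genes or 71.1% of those tested. Most of these differences were small: 467 genes rose and 727 fell by at least 2-fold, and 106 rose and 269 fell by at least 4-fold. The median absolute log2 fold change was 0.29. In 72.7% of the tested genes the 3 values of one group lay wholly above those of the other, where chance gives 10%. When the fold change was itself tested against 1.5 (glmTreat), 1684 genes passed, 735 higher and 949 lower.

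The 10 largest rises with at least 100 counts were led by Tnxb, which encodes the matrix protein tenascin X, from 0.149 CPM ± 0.0545 to 8.38 CPM ± 0.450 (SD, n = 3 each), a log2 fold change of 5.75 (SE 0.23, edgeR adjusted p = 1.59e-19). Cavin2, a coat protein of caveolae, rose from 1.36 CPM ± 0.362 to 74.3 CPM ± 0.433 (SD, n = 3 each), by 5.74 (SE 0.088, edgeR adjusted p = 2.59e-29). Cntfr, the receptor subunit for ciliary neurotrophic factor, rose by 5.68 (SE 0.29; 6.31 without control replicate 1) from 7 counts over the 3 control libraries. Others were the proprotein convertase Pcsk6 (3.66), the kallikrein Klk10 (3.42), the CD47 receptor Sirpa (3.42), the FGF carrier Fgfbp1 (3.41), the annexin Anxa8 (3.40) and the endocytic adaptor Dab2 (3.32), with SEs between 0.053 and 0.091.

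The 10 largest falls ended near or at 0 counts. Rasef, a GTPase of the Rab family, had 495, 547 and 438 counts in the controls and 0 in each ETV4 KO library, at least 522.3-fold lower with 3 counts over the group as the floor. The heparan sulfate proteoglycan Gpc4 fell at least 255.1-fold and Epdr1 at least 122.1-fold, both also to 0 counts in ETV4 KO. Zfp518b, a zinc finger gene, kept 1 count, in ETV4 KO replicate 3, against 1289 in controls, a ratio of 1364.6 with a 95% counting interval of 244.5 to 53939, and the acyl-CoA synthetase Acsl6 kept 3 against 529, a ratio of 186.7 with an interval of 63.5 to 908.1. Rab25, a GTPase of epithelial recycling endosomes, fell from 49.2 CPM ± 0.596 to 0.221 CPM ± 0.176 (SD, n = 3 each), a log2 fold change of -7.69 (SE 0.14, edgeR adjusted p = 3.19e-28). Its 18 remaining counts were 12, 4 and 2 in ETV4 KO replicates 1, 2 and 3, and without replicate 1 the log2 fold change was -8.58. Tmem266 (-8.03), Fam111a (-7.75), Bspry (-7.75) and the ribosomal S6 kinase gene Rps6ka6 (-7.56) completed the group, with 5 to 9 counts left over the 3 ETV4 KO libraries; Fam111a had -7.12 without ETV4 KO replicate 1 and -8.45 without ETV4 KO replicate 2.

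**Figure D2:**
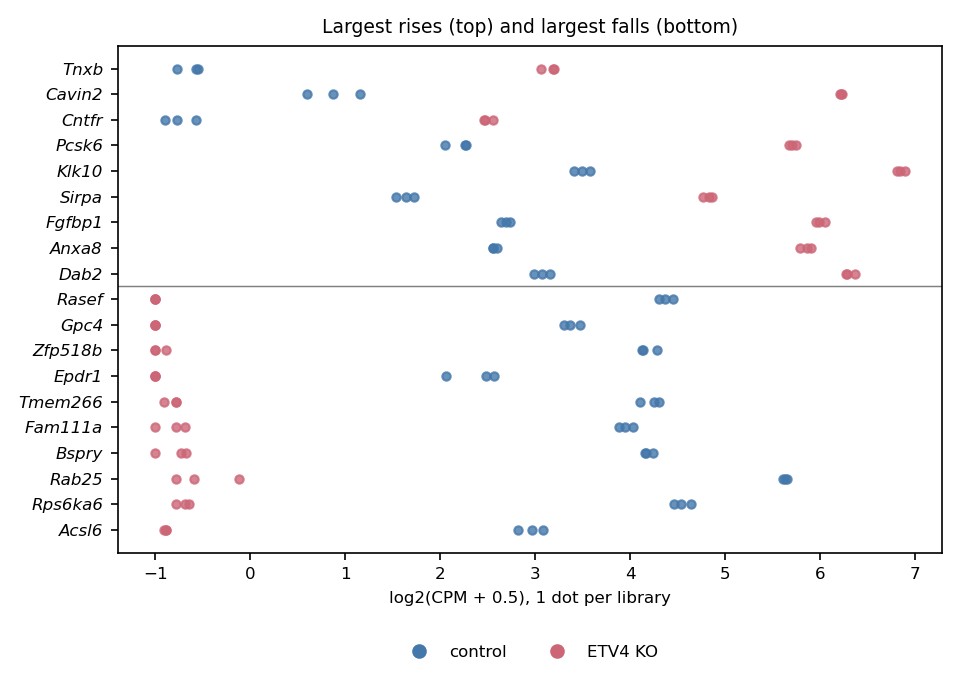
log2(CPM + 0.5) of 9 of the 10 genes with the largest rises (top) and the 10 with the largest falls (bottom), 1 dot per library, controls in blue and ETV4 KO in red. The groups do not overlap for any of the genes shown; Rasef, Gpc4 and Epdr1 sit at 0 counts in each ETV4 KO library.

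Gene lists fixed before the data were examined were used to group the changes. Of 38 lists 34 had at least 5 tested members, and camera with its preset correlation of 0.01 called 15 of them, 9 higher and 6 lower in ETV4 KO. With an estimated correlation camera called 0 lists, the smallest adjusted p being 0.127, while 8 lists had an unadjusted p under 0.05; the directional test fry, which asks only whether a list's own genes move one way, called 29. Counts of changed members use the p adjusted over all genes. Adjusted over the list alone, the counts were identical except for 1 more higher member in the list of NRF2 and oxidative stress genes and in that of semaphorins, ephrins and guidance receptors. The 126 genes that the naming rule took from the lists had SEs of the log2 fold change between 0.029 and 0.20 and edgeR adjusted p-values of at most 0.0031, and for each of the 126 the groups did not overlap.

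Interferon-stimulated genes were lower almost throughout. Of 27 tested members 25 fell and 1 rose, with a median log2 fold change of -1.55 (camera adjusted p = 1.36e-09; adjusted p = 0.127 with an estimated correlation). Parp14 went from 30.7 CPM ± 0.875 to 8.34 CPM ± 0.414 (SD, n = 3 each), a log2 fold change of -1.88, Ifi27 had -1.55 and Ifi35, which lies on chromosome 11, -1.38. Ifit2 rose by 0.40, a call that was lost with the 10 Mb bin medians taken out (log2 fold change 0.23, adjusted p = 0.0879). The 1 member that did not pass, named after its value was seen, was Oasl1 with -0.20 (SE 0.13, edgeR adjusted p = 0.155). Oasl1 was called lower with the bin medians taken out, with -0.41 (adjusted p = 0.00653), and there Ifi35 had -0.92. Under that setting 25 of the 27 tested members were called lower and 0 higher. In the antigen presentation list 15 of 17 tested members fell and 0 rose, with a median of -1.25 (camera adjusted p = 9.85e-07; adjusted p = 0.153 with an estimated correlation). Psmb8 and Psmb10, subunits of the immunoproteasome, had -3.30 and -1.25, and the peptide transporter subunit Tap2 had -1.77. The pair that did not pass, also named after their values were seen, were B2m, the light chain of MHC class I, at 0.01 (SE 0.034, edgeR adjusted p = 0.841) and Tapbp at 0.02 (SE 0.036, edgeR adjusted p = 0.676); the sign of both changed with upper-quartile factors and with library size alone. With the bin medians taken out B2m (-0.18, adjusted p = 3.06e-05) and Tapbp (-0.29, adjusted p = 3.97e-08) were called lower, as were all 17 tested members of the list. Calls under this step treat the local median as known, without the spread of the genes around it. Psmb8, Tap2, Tapbp and the H2 genes lie on chromosome 17, whose expressed genes had a median of 0.37. Reads of the near-identical H2 genes can be split between copies, so their values are uncertain. The interferon genes Ifnb1, Ifnl2, Ifnl3 and Ifna4 had 0 counts over the 6 libraries and Ifng had 1.

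Camera called none of 3 other inflammatory lists. Among chemokines and cytokines 9 of 23 tested members rose and 11 fell (camera adjusted p = 0.736): Cxcl1, a neutrophil chemokine, rose by 1.14, while Il23a, Il18 and Cxcl16 had -1.01, -2.97 and -0.57. Cxcl16 lies on chromosome 11 and had -0.17 with the 10 Mb bin medians taken out. Among NF-kB target genes 4 of 19 rose and 12 fell (camera adjusted p = 0.678; called lower by fry, 0.0205). The NF-kB inhibitors Tnip1 and Tnfaip3 had -0.85 and -0.61 and Traf1 had -0.54, while Ptgs2, which encodes cyclooxygenase, rose by 1.31 from 360.1 CPM to 895.0 CPM. Among genes of cytosolic DNA sensing and the nuclear envelope 9 of 20 rose and 6 fell (camera adjusted p = 0.397; called higher by fry, 0.000956), with Lemd2, Ankle2 and Sun2 at 0.65, 0.41 and 0.28 and Lemd3 at -0.26. Lemd2, Ankle2, Sun2 and Lemd3 had 0.29, 0.21, 0.18 and -0.15 with the bin medians taken out, and Tnip1 and Tnfaip3 had -0.51 and -0.36.

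More epithelial genes fell than rose, and more mesenchymal genes rose than fell. Of 30 tested members of the epithelial identity and junction list 17 fell and 5 rose, with a median of -0.20 (camera adjusted p = 2.28e-08; adjusted p = 0.127 with an estimated correlation); with the 10 Mb bin medians taken out 23 fell and 4 rose, with a median of -0.33. The tight junction gene Cldn7 went from 191.9 CPM ± 6.37 to 3.16 CPM ± 0.192 (SD, n = 3 each), a log2 fold change of -5.92 (SE 0.061, edgeR adjusted p = 4.69e-34). Rab25 had -7.69 and Epcam, a surface adhesion protein of epithelia, -1.37, while the claudin Cldn4 rose by 0.47 (0.24 with the bin medians taken out). Of 15 tested mesenchymal and EMT genes 10 rose and 3 fell, with a median of 0.32 (camera adjusted p = 3.92e-05; adjusted p = 0.127 with an estimated correlation). The matrix protein Sparc rose by 2.35, the intermediate filament Vim by 1.08 from 1200.7 CPM ± 47.2 to 2534.1 CPM ± 47.3 (SD, n = 3 each), and the galectin Lgals1 by 0.81; the tropomyosin Tpm1 had -0.45. Of these 15 genes 4 rose and 2 fell by at least 2-fold. Postn, named after its value was seen, was 1 of these falls, at -1.48. Basal mammary genes rose in 2 and fell in 4 of 7 (camera adjusted p = 0.861; called by fry, 0.0249; 2 rose and 2 fell with the 10 Mb bin medians taken out), with Itga6 at 1.38 and Lgr6, Itgb4 and Krt14 at -0.83, -0.44 and -0.41. Itgb4 and Krt14 lie on chromosome 11, and with the 10 Mb bin medians taken out their log2 fold changes were 0.05 and 0.06. Luminal mammary genes rose in 3 and fell in 6 of 9 (camera adjusted p = 0.861), with Areg, an EGF receptor ligand, at 1.26 and the keratins Krt8 and Krt18 and the oestrogen receptor Esr1 at -0.48, -0.42 and -0.84.

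Genes for matrix and matrix-degrading enzymes were more often higher than lower. Among matrix metalloproteinases and proteases 14 of 20 rose and 6 fell, with a median of 0.43 (camera adjusted p = 0.000197; adjusted p = 0.164 with an estimated correlation). Mmp3 (stromelysin) rose by 2.36 from 23.8 CPM to 122.2 CPM, Adamts1 by 1.47 and the cathepsin Ctsb by 0.87, whereas Mmp9 (a gelatinase) had -1.27, from 308.4 CPM to 127.6 CPM. Protease inhibitors rose in 4 and fell in 3 of 9 (camera adjusted p = 0.222; called by fry, 0.000477; 4 rose and 4 fell with the bin medians taken out): Timp1 rose by 0.84 and Timp2 by 0.50, while Serpinb5 (maspin) had -1.82. With the bin medians taken out Timp2, on chromosome 11, had 0.99. Among collagens and basement membrane genes 12 of 23 rose and 4 fell, with a median of 0.11 (camera adjusted p = 0.00151; adjusted p = 0.439 with an estimated correlation; median 0.07 with the bin medians taken out), including the fibrillar collagen Col5a1 at 3.01 and the laminin Lamb3 at 0.67, with Thbs1 at -0.45. Integrin and focal adhesion genes rose in 11 and fell in 8 of 24 (camera adjusted p = 0.222; called higher by fry, 0.00355), with Itga6, Itga5 and the focal adhesion kinase Ptk2 at 1.38, 0.95 and 0.58 and Itgb6 at -1.70.

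**Figure D3:**
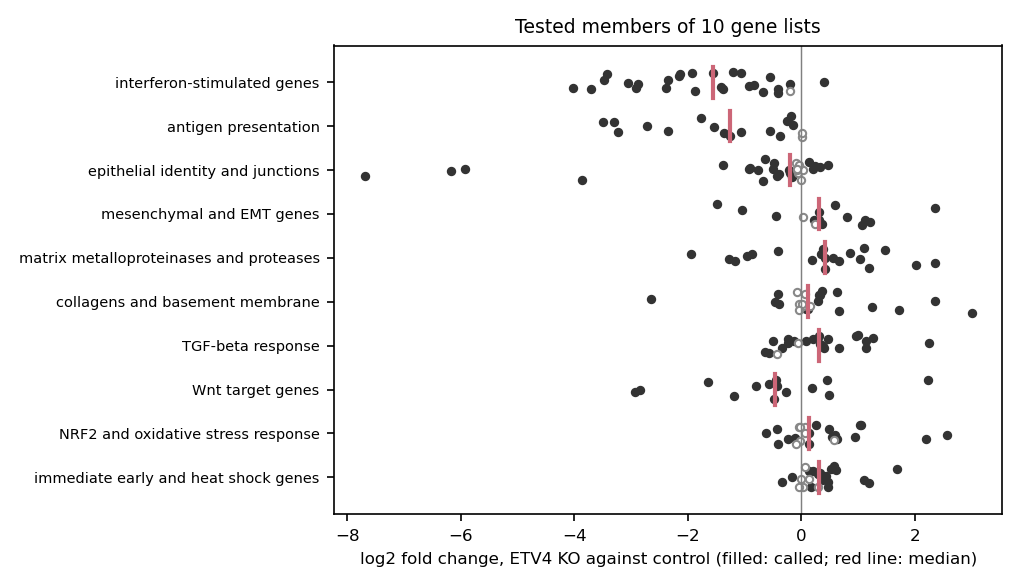
Log2 fold changes (ETV4 KO against control, horizontal axis) of each tested member of 10 gene lists called by camera with the preset correlation, 1 dot per gene, filled where the gene was called, with the list median as a red line; the vertical scatter within a list has no meaning. The medians range from -1.55 for interferon-stimulated genes to 0.43 for matrix metalloproteinases and proteases, and each list other than antigen presentation holds called members in both directions.

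Genes downstream of ERK signalling and of the growth factor receptors went both ways. The list of PEA3 family and ERK feedback genes had 11 of 20 members higher and 8 lower (camera adjusted p = 0.357; called higher by fry, 0.00322). The ERK phosphatase Dusp5 rose by 1.23, Ier3 by 0.82 and the AP-1 gene Fosl1 by 0.58, while the ephrin receptor Epha4 had -1.05. Ier3 had 0.53 with the bin medians taken out. Ligands and receptors of the FGF, EGF and HGF families rose in 5 and fell in 6 of 14 (camera adjusted p = 0.925), with Areg at 1.26 and Erbb3, Erbb2 and the EGF family ligand Btc at -1.28, -0.56 and -1.13. Erbb2, on chromosome 11, had -0.20 with the bin medians taken out. TGF-beta response genes rose in 14 and fell in 7 of 23, with a median of 0.32 (camera adjusted p = 0.00046; adjusted p = 0.261 with an estimated correlation); the latent TGF-beta binding proteins Ltbp2 and Ltbp4 had 1.00 and 1.15, and the signal transducer Smad3 had -0.64. This call was lost with limma-voom (adjusted p = 0.0523). Wnt target genes fell in 10 and rose in 4 of 14, with a median of -0.46 (camera adjusted p = 0.006; adjusted p = 0.178 with an estimated correlation; 0.0855 with limma-voom); with the bin medians taken out 6 fell and 3 rose, with a median of -0.23. The members with the smallest p, Sfrp1 at -2.83, Apcdd1 at -1.19 and Notum at -2.92, encode secreted or membrane-bound inhibitors of Wnt signalling, and the ligand Wnt7a rose by 0.49. Notch pathway genes rose in 6 and fell in 5 of 12 (camera adjusted p = 0.741; called by fry, 0.0317), with the ligand Jag1 at -1.46 and Jag2, Notch1 and Dll4 at 1.11, 0.90 and 0.93. YAP and SRF target genes rose in 13 and fell in 3 of 19 (camera adjusted p = 0.0655; 0.261 with an estimated correlation; called higher by fry, 3.00e-05; 0.0248 with limma-voom, 0.0363 without a low-count filter and 0.0381 with a replicate block), with Axl, Crim1 and Arhgef17 at 0.59, 0.67 and 0.66 and the calponin Cnn2 at -0.72. Crim1 and Arhgef17 had 0.25 and 0.41 with the bin medians taken out. When newer symbols were matched to the older ones of the table, a step added after seeing which symbols were absent, this list was called (camera adjusted p = 0.00143; adjusted p = 0.107 with an estimated correlation). The matched YAP targets were Cyr61, which rose by 1.74 (SE 0.036), and Ctgf, which rose by 0.82 (SE 0.053). Semaphorins, ephrins and guidance receptors rose in 14 and fell in 9 of 27 (camera adjusted p = 0.719), with Nrp1, Efnb1 and Efna5 at 1.94, 0.69 and 0.78 and the netrin Ntn1 at -1.67. Of these 27 genes 1 rose and 6 fell by at least 2-fold. Efna5, on chromosome 17, had 0.19 with the bin medians taken out.

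Of 7 stress and metabolic lists, camera called those of NRF2 and of fatty acid synthesis. Among NRF2 and oxidative stress genes 12 of 24 rose and 5 fell, with a median of 0.14 (camera adjusted p = 6.88e-05; adjusted p = 0.127 with an estimated correlation): the glutathione transferase Gsta4 rose by 2.58 (SE 0.045), the heme oxygenase Hmox1 by 2.20 and the ferritin Fth1 by 0.95, while the glutathione reductase Gsr had -0.62. Reads of the glutathione transferase family can be shared between copies. Genes of fatty acid synthesis and lipid storage fell in 12 and rose in 7 of 22, with a median of -0.18 (camera adjusted p = 0.0268; adjusted p = 0.249 with an estimated correlation), a call lost with limma-voom (0.0854) and with the bin medians taken out (0.0739, median -0.11). Acsl4 had -1.19, Srebf1 and Fasn, both on chromosome 11, had -0.77 and -0.65, and Acsl1 rose by 0.67; with the bin medians taken out Srebf1 and Fasn had -0.41 and -0.14. Cholesterol synthesis genes fell in 15 and rose in 5 of 23 (camera adjusted p = 0.0706; called lower by fry, 0.000292), with Pmvk and Lss at -0.90 and -0.56 and Ebp at 1.06. This list was called with DESeq2 (0.0229), with limma-voom (0.046), without a low-count filter (0.0363), with library size alone (0.0463), with a replicate block (0.0381) and with the bin medians taken out (0.00184), and not with an estimated correlation (0.457). Ebp, on chromosome X, had 0.15 and Lss had -0.36 with the bin medians taken out. Hypoxia and glycolysis genes rose in 16 and fell in 8 of 31 (camera adjusted p = 0.159; 0.0255 with DESeq2; 0.688 with an estimated correlation; called higher by fry, 0.00314), with Ndrg1, Pdk1 and Vegfa at 0.93, 0.93 and 1.01 and Ddit4 at -1.36. Of these 31 genes 1 rose and 4 fell by at least 2-fold. Genes of ATF4 and the unfolded protein response rose in 17 and fell in 5 of 28 (camera adjusted p = 0.115; 0.535 with an estimated correlation; called higher by fry, 0.000956; 0.0301 with DESeq2, 0.046 with limma-voom and 0.0335 with the bin medians taken out), with Calr, Chac1 and Hspa5 at 0.77, 1.48 and 0.41 and Nupr1 at -1.30. Hspa5 had 0.24 with the bin medians taken out. Among p53 target genes 11 of 20 fell and 5 rose (camera adjusted p = 0.441; called lower by fry, 0.0160; 7 fell and 7 rose with the bin medians taken out), with Ddit4, Phlda3 and Xpc at -1.36, -0.69 and -0.70 and Plk2 at 0.58. Nuclear-encoded respiratory chain genes rose in 11 and fell in 9 of 29 (camera adjusted p = 0.723), and in 6 and 8 with the bin medians taken out. Ndufa1 and Cycs had 0.48 and 0.23, Ndufb3 had -0.42, and Ndufv2, on chromosome 17, had 0.45, which became -0.17 with the bin medians taken out, while Ndufa1 and Cycs had 0.25 and 0.47.

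Cell cycle genes were modestly higher and ribosomal protein genes modestly lower. Genes of the G2 and M phases rose in 22 and fell in 4 of 30, with a median of 0.24 (camera adjusted p = 0.0015; adjusted p = 0.384 with an estimated correlation), including Ccnf at 0.82, the proliferation marker Mki67 at 0.74 and Anln at 0.54, with Ccnb2 at -0.27. S phase genes rose in 17 and fell in 7 of 26, with a median of 0.17 (camera adjusted p = 0.0407; adjusted p = 0.298 with an estimated correlation; with the bin medians taken out 15 rose and 4 fell, with a median of 0.11), including Pola1, Rrm2 and Uhrf1 at 0.95, 0.83 and 0.53. The S phase call was lost without control replicate 2 (0.0511), without ETV4 KO replicate 3 (0.0534) and under 3 other settings, with adjusted p-values up to 0.0685. Tk1, on chromosome 11, had -0.36, which became 0.14 with the bin medians taken out, and Uhrf1, Ccnf and Ccnb2 had 0.20, 0.46 and -0.16. Cytosolic ribosomal protein genes fell in 22 and rose in 3 of 36, with a median of -0.14 (camera adjusted p = 0.0255; adjusted p = 0.738 with an estimated correlation), and this call was lost without control replicate 2 (0.0542). Rps20, Rpl23 and Rpl22 had -0.49, -0.54 and -0.55, and Rps2, on chromosome 17, rose by 0.70. With the bin medians taken out Rps2 had 0.34 and Rpl23, on chromosome 11, had -0.17.

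Of 4 lists for handling and RNA quality, camera called the immediate early and heat shock list and the mitochondrial list. Immediate early and heat shock genes, which respond within minutes to handling such as enzyme digestion, rose in 17 and fell in 2 of 25, with a median of 0.31 (camera adjusted p = 2.18e-06; adjusted p = 0.127 with an estimated correlation; median 0.20 with the bin medians taken out). Hsph1, Dusp1 and Nr4a1 had 1.69, 1.10 and 1.19, and Junb had -0.33 (-0.17 with the bin medians taken out). Mitochondrially encoded transcripts rose in 7 and fell in 0 of 9, with a median of 0.49 (camera adjusted p = 0.0015; adjusted p = 0.457 with an estimated correlation), with mt-Nd1, mt-Nd5 and mt-Nd6 at 0.67, 0.73 and 0.79. Their share of the counts was 1.80% to 1.96% in controls and 2.27% to 2.51% in ETV4 KO. mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 had 22, 6, 39 and 12 counts over the 6 libraries, so the mitochondrial values leave out abundant transcripts and are uncertain. Nuclear-retained and non-polyadenylated RNAs rose in 3 and fell in 0 of 5 (camera adjusted p = 0.0783; called higher by fry, 0.0106), with Neat1, Kcnq1ot1 and Malat1 at 0.70, 1.18 and 0.27 (Malat1 0.17 with the bin medians taken out). Without ETV4 KO replicate 1 this list was called (0.0325), and it was called with DESeq2 (0.0429) and with a replicate block (0.0169), and not with an estimated correlation (0.535). The list of replication-dependent histones had 1 of 6 members higher and 2 lower (camera adjusted p = 0.336; called by fry, 0.00294), with Hist1h4i at 0.51, Hist1h1c at -1.16 and H1f0 at -0.50. H1f0 is on this list although its transcript is polyadenylated and also made outside S phase, so 1 of the 2 falls does not bear on this class. The strand setting of the counting is not given in the sources used here, so genes with an antisense or overlapping partner, such as Kcnq1ot1 and mt-Nd6, are uncertain.

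**Figure D4:**
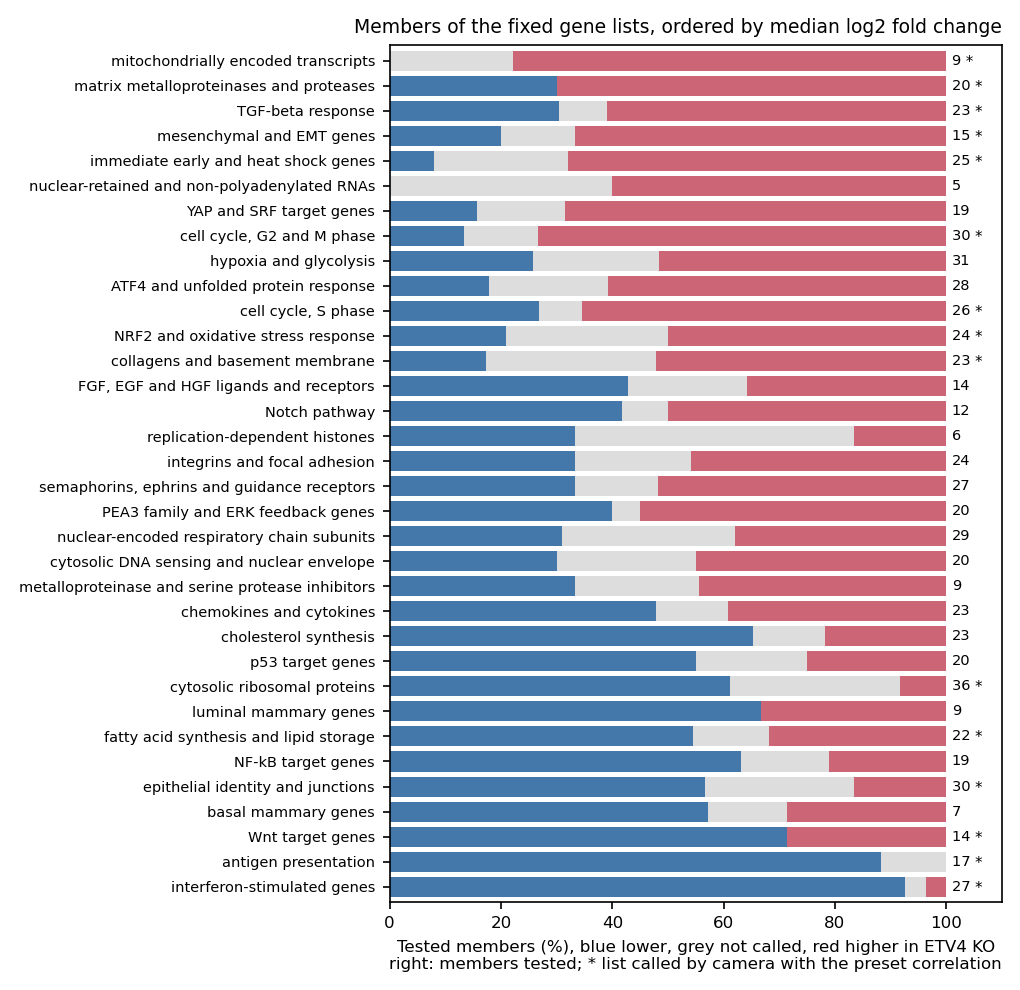
Share of the tested members (horizontal axis, %) of each of the 34 tested lists that were called lower (blue), not called (grey) or called higher (red) in ETV4 KO, with the number of tested members at the right and * for the 15 lists that camera called with the preset correlation. Interferon-stimulated genes (25 of 27 lower) and antigen presentation (15 of 17 lower) stand at the bottom of the order by median log2 fold change.

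Markers of other cell types had too few tested members for a list test. Leukocyte markers summed to 10.97 CPM ± 0.287 in controls and 10.4 CPM ± 1.31 in ETV4 KO (SD, n = 3 each), 14 of the 15 lying under 1 CPM. Cd68 accounted for most of this sum, at 9.55 CPM and 9.84 CPM, a log2 fold change of 0.05 (SE 0.091, edgeR adjusted p = 0.616) that became 0.42 (adjusted p = 0.000212) with the bin medians taken out. Fibroblast markers summed to 14.2 CPM ± 0.608 and 14.5 CPM ± 1.05, with 13 of 15 under 1 CPM, and adipocyte and muscle markers to 0.962 CPM ± 0.405 and 0.987 CPM ± 0.329, with all 12 under 1 CPM. Among fibroblast markers Pdgfra rose by 0.32 (SE 0.083) and Postn fell by 1.48 (SE 0.21); the call of Pdgfra was lost with the bin medians taken out (0.18, adjusted p = 0.0600). Endothelial markers summed to 98.4 CPM ± 2.56 and 134.4 CPM ± 3.78, carried by Flt1 and Eng, while Pecam1 had 19 counts over the 6 libraries. Eng rose by 0.81 (SE 0.043) and Flt1 by 0.22 (SE 0.047); the log2 fold change of Flt1 was -0.00022 with the bin medians taken out. These genes, apart from the list members at low counts, were named after their values were seen.

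Fold changes also differed by chromosome, a comparison made after seeing the data. Over 764 expressed genes of chromosome 11 the median log2 fold change was -0.38 (95% bootstrap interval -0.41 to -0.36), and 89.8% of these genes lay below 0. Chromosome 17 had a median of 0.37 (0.33 to 0.41) over 447 genes, with 87.7% above 0. Chromosome 16 had -0.24 (-0.29 to -0.20) and chromosome 5 had 0.23 (0.20 to 0.26). Within chromosome X the bins from 0 to 10 Mb and 10 to 20 Mb had medians of 0.92 and 0.71, against -0.06 from 20 to 30 Mb. On chromosome 2 the bin from 150 to 160 Mb had 0.17 and the next had -0.17; on chromosome 9 the bin from 90 to 100 Mb had -0.35 and the next had 0.08. The 3 libraries of a group gave nearly equal medians: for chromosome 11 those of ETV4 KO were -0.38, -0.37 and -0.37 relative to the control mean, and for chromosome 17 they were 0.35, 0.38 and 0.36. With the bin medians taken out 7820 genes were called, 3687 higher and 4133 lower, of which 6369 were also called without this step and 5958 of those in the same direction.

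**Figure D5:**
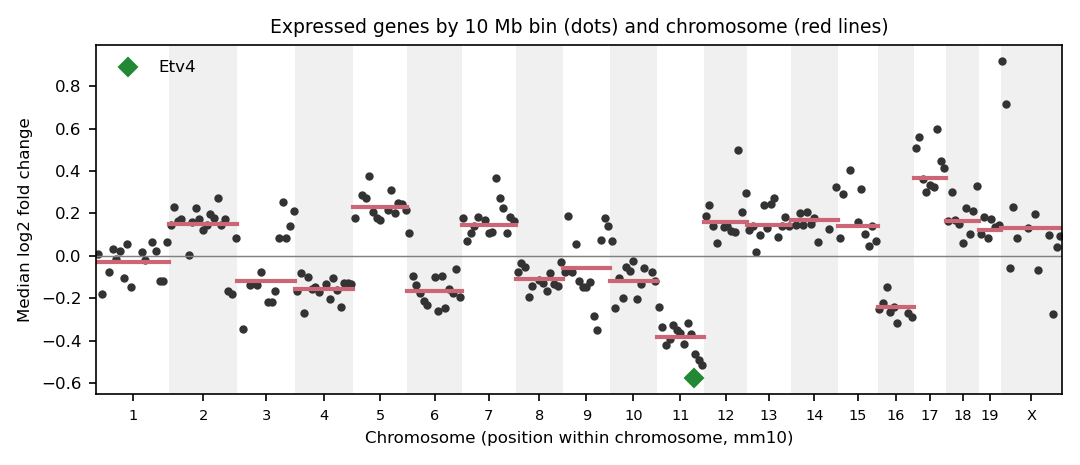
Median log2 fold change (ETV4 KO against control, vertical axis) of expressed genes in bins of 10 Mb along each chromosome (dots) and over each whole chromosome (red lines), with Etv4 as a green diamond; positions are those of mm10. Chromosome 11 lies at -0.38 and chromosome 17 at 0.37, and Etv4 at -0.58.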

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

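The 10 Mb bin medians, the match of newer symbols (with either correlation) and fry for each list were chosen after the results were seen; the other settings were planned. Against 8582 genes called, the other scalings, tests, filters and single-sample omissions called 7825 to 8880, and an adjusted p under 0.01 left 7575. With at least a 2-fold change these settings called 946 to 1594 genes against 1194. The log2 fold change of Etv4 stayed between -0.63 and -0.56 under the planned settings. Library size alone moved the median of all genes to -0.05 and the share of called genes that were higher from 49.3% to 42.8%. glmTreat against a fold change of 1.5 called 1684 genes, since it tests a larger change. Against 15 lists, camera with an estimated correlation called 0, where the main test preset the correlation at 0.01. The test fry, which does not compare a list with other genes, called 29. Omitting 1 sample left 13 to 16 lists.

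The log2 fold change of B2m, not called in the main test, became -0.029 with upper-quartile factors, -0.043 with library size alone and -0.18 with the bin medians taken out, where it was called lower, and ranged from -0.017 to 0.031 with 1 sample left out. Tapbp became -0.020, -0.034 and -0.29 under the same 3 settings, the last a call, with a range of -0.012 to 0.040 with 1 sample left out, and Cd68 ranged from -0.048 to 0.10 with 1 sample left out and was called higher, at 0.42, with the bin medians taken out. With the bin medians taken out Itgb4 had 0.053, Krt14 0.059, Tk1 0.14, Ndufv2 -0.17 and Flt1 -0.00022, since the local median is subtracted. Otherwise the cause was not tested.

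Whether replicate numbers pair the samples is unclear: deviations from the group mean had r of 0.071, 0.0705 and 0.0186 for equal numbers and -0.0863 to 0.0199 for unequal ones, and 5 of the 6 samples agreed best with their own number. A block on them called 8882 genes and added the YAP and SRF (0.0381), cholesterol (0.0381) and nuclear-retained (0.0169) lists. Gsta2 and the histone list have no value under the CPM filter. Depth limits genes with few counts, as the simulation showed.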

Other observations

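The tests of the arrangement of genes along the genome, of a single ETV4 KO population, of Etv4 against chromosome 11 dosage, of leukocytes and of library totals were chosen after their results were seen, and the genes and the definition of lost genes below were chosen after seeing the data. Some genes of caveolae, the membrane pits built from caveolins and cavins, were looked at without a fixed list or a list test. Cav1 fell from 30.4 CPM ± 0.290 to 0.272 CPM ± 0.0666 (SD, n = 3 each), a log2 fold change of -6.78 (SE 0.14), and Cavin1, on chromosome 11, had -1.23 (SE 0.032; -0.77 with the 10 Mb bin medians taken out), while Cavin2 rose by 5.74 (SE 0.088). Cavin3 had -0.11 (SE 0.037) and Cav2 -0.10 (SE 0.042), a call that 7 of 14 settings kept; with the bin medians taken out Cavin3 had -0.39 (adjusted p = 2.53e-10) and Cav2 -0.0095 (adjusted p = 0.855). The secreted BMP antagonists Nog, Chrd and Fst rose by 3.80 (SE 0.38), 4.86 (SE 0.45; 6.01 without control replicate 2) and 3.01 (SE 0.37), from levels under 0.2 CPM to 1.77, 1.72 and 1.34 CPM.

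Only 1 of the 10 splits of the 6 samples into 3 and 3, the real one, called as many as 8582 genes, the highest other count being 0, and 10 splits are too few for a share under 0.05. The other splits put samples of both groups on each side, so the group difference widened their spread. Their count of 0 therefore adds no separate evidence. The SD of the chromosome medians was 0.188 against at most 0.0357 in 1000 random reassignments, which argues against chance arrangement. After the bin medians were taken out 7820 genes were called, 1109 of them at least 2-fold. That step can make calls of its own: 5958 of the 7820 were called in the same direction without it. Of the 2-fold calls 1001 were also made without it. The kept 2-fold calls argue against the median shift at a gene's own position as the whole cause. The step treats that median as known and takes out nothing else, so other effects of changed chromosome content stay open. Etv4 stood at percentile 27.4 of the expressed genes within 10 Mb, so its lower mRNA is consistent with lower dosage of chromosome 11. Whole chromosomes moved together, with 89.8% of the expressed genes of chromosome 11 below 0 and 87.7% of those of chromosome 17 above 0. On chromosome X the bin median stepped from 0.71 to -0.06. With the SD above, this argues against changes gene by gene, without regard to position, as the source of the chromosome pattern. No DNA was measured here, and whether that pattern arose through loss of ETV4 or apart from it cannot be told. Nor can loss of ETV4 and a single ETV4 KO population with other chromosome content be told apart for the other changes. The ETV4 KO samples share 1 library code.

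The fall of interferon-stimulated and antigen presentation genes stayed at a median of -1.48 with the bin medians taken out. Under the scaling nearest to 0 it was -1.40. This argues against library scaling, and against shifts at the members' own positions, as its whole cause. The bin step takes out only the local median, so effects of genes elsewhere whose dosage changed were not tested and stay open. The summed CPM of 7 leukocyte genes in the controls was 0.213, against a summed fall of 412.5 CPM in the members. These 7 genes were picked after their values were seen and leave out Cd68, so their low sum decides little. All 15 markers of the leukocyte list, fixed beforehand, summed to 10.97 CPM in controls and 10.4 CPM in ETV4 KO. This sum is also far below the fall, which argues against leukocytes in the control cultures as its whole cause. Loss of ETV4 remains an untested explanation, confounded with the shared library code.

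In 22 called genes with at least 100 mean counts in controls the log2 fold change was -5 or less; 21 of them had under 1 CPM in ETV4 KO, while Cldn7 kept 3.16 CPM. Both nearest tested neighbours lay above -1 for 15 of the 22, which leaves no sign there of a deletion that reaches those neighbours. Some neighbours were far away, such as 2293 kb and 923 kb for Rps6ka6, so a deletion over untested genes in between would not show. The median of all 44 neighbours was -0.19, but this median, the bound set beforehand, cannot decide single loci: 8 neighbours lay below -1, and Kazn beside Tmem51 and Casp4 beside Casp12 went from 56 to 0 and from 59 to 1 counts over a group, so such deletions stay open there, and smaller ones were not tested. The smallest ETV4 KO library held 0.913 of the total counts of the largest control library, where depth would need at most 1/32, which argues against depth. Loss of ETV4 and an origin of the ETV4 KO samples in other cells of the line stay open and were not tested, as these samples share 1 library code.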
